A study of Mus musculus with 6 samples.

How the data were processed

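Ovaries of BDF1 mice were profiled by mRNA sequencing. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a SMARTer mRNA kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2 and quantified with StringTie on mm10; versions, the annotation and strand settings are not given in the sources used here. Each library came as a StringTie gene table of 45781 or 45782 rows. The deposited TPM values, per the file headers, are length-scaled abundances that sum to a constant total per file. The deposited FPKM values, per the file headers, are scaled for transcript length and fragment number, and TPM divided by FPKM was a single constant per file, from 1.89 to 2.31. The deposited coverage signal, per the file headers, is the mean read depth over a gene, and it was used only to estimate depth: coverage divided by FPKM took 1 shared value in 29.9% to 31.7% of genes, which corresponds to 6.34 to 7.14 gigabases of aligned reads per library. No read counts were used here, so precision is known only from the spread between libraries and count models were not applied.

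The files identify genes by NCBI Gene ID. Symbols were taken from a RefSeq gene table of assembly GRCm38.p6, matched on Gene ID: 45683 or 45684 rows per library matched and 98 did not. The unmatched rows held 0.0145% to 0.0301% of TPM and were left out of the tests. Values of 1 symbol were summed. Coordinates are those of the files, on mm10. Reads of pseudogenes, paralogs and overlapping genes may be divided between copies, and without a stated strand setting antisense partners cannot be separated.

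Groups were taken from the labels alone: young PBS, old PBS and old MIT-001, 2 libraries each. Genes with a TPM of at least 1 in at least 2 libraries were tested (16473 genes). Values were analysed as log2(TPM + 1), so fold changes are on that scale and understate the change of genes with low values. A linear model with 1 mean per group was fitted to all 6 libraries with limma 3.58.1 (R 4.3.3), with an intensity trend in the empirical Bayes step, which gave 3 residual and 3.12 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes were called at an adjusted p below 0.05. Errors of fold changes are standard errors, and errors of TPM are standard deviations of 2 libraries.

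A total of 36 gene lists were fixed before the data were examined, 18 of cell types and 18 of pathways, holding 548 genes, all found in the files (15 through an older or mitochondrial name). Lists with at least 3 genes tested were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again by camera with an estimated correlation and by fry, which asks whether the genes of a list move on balance in a single direction. No list passed camera with an estimated correlation in any comparison (smallest adjusted p 0.081, 0.175 and 0.276). Several lists share genes, such as the C1q genes of the macrophage and complement lists.

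Named genes were chosen by a rule fixed before the data were examined: among called genes with a mean TPM of at least 5 in the higher group and no overlap between the groups' libraries, the 10 with the largest log2 fold change in each direction, without clone names and with at most 2 immunoglobulin segments and 2 genes of a paralog family. Where fewer than 5 genes were called in a direction, the same rule was applied to an unadjusted p below 0.05 and the genes are named as not passing. Up to 4 members with the smallest p were named per list. A gene that met this rule is not reported here. Members named for lists that did not pass, and the members named for the check of labels and in the account of the opposed fold changes, were partly chosen after their values were seen.

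The procedure was tested on simulated data with 200 of 16473 genes changed. The changed genes were drawn from those with a mean log2(TPM + 1) of at least 3, and genes varied independently. Recovery was therefore not measured for genes with lower values or for genes that vary together. For old PBS against young PBS, 4%, 80%, 94% and 100% of genes changed by a log2 size of 1, 2, 3 and 4 were recovered, with 12 wrong calls among 151. For old MIT-001 against old PBS the shares were 2%, 86%, 98% and 98%, with 10 wrong among 152, and for old MIT-001 against young PBS 8%, 86%, 96% and 100%, with 9 wrong among 154. The opposition of fold changes was compared with 1000 simulations in which the groups shared a mean and had the fitted residual spread, with each gene drawn independently. Shared calls were compared with 100 such simulations of all 6 libraries, and with 20 for each library left out, refitted with limma.

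Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a filter at a TPM of 5, FPKM, median centring, quantile normalization, TPM rescaled without immunoglobulin, haemoglobin and mitochondrial genes, no trend, array quality weights, the replicate number as a block, only the 2 groups compared, other call thresholds, and each library left out in turn. A group left with 1 library was assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.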

Results

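Messenger RNA was sequenced from ovaries of BDF1 mice, a hybrid laboratory strain. The labels give 3 groups of 2 libraries: mice of 8 weeks given PBS, mice of 65 weeks given PBS, and mice of 65 weeks given MIT-001, a mitochondria-targeted scavenger of reactive oxygen species (0.5 mg/kg into the abdomen for 7 days). The files held gene abundances in TPM (transcript abundance scaled for length and library), and between 14317 and 16304 genes per library reached a TPM of 1. The deposited coverage and FPKM implied 6.34 to 7.14 gigabases of aligned reads per library, so depth was similar across libraries. The labels do not say which animals, or how many, gave each library, so p-values measure the spread between these libraries only.

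The age labels were checked first, with oocyte, granulosa cell and plasma cell genes, and the values went against them. Gdf9, an oocyte growth factor, was at 116 and 108 TPM in the libraries labelled old PBS, but at 73.3 and 9.51 TPM in those labelled young PBS. Amh, made by granulosa cells of growing follicles, was at 123 and 213 TPM in the libraries labelled old PBS and at 95.0 and 40.1 TPM in those labelled young PBS. Igkc, the immunoglobulin kappa constant region, was at 9.50 and 10.6 TPM in the libraries labelled old PBS and at 1340 and 174 TPM in those labelled young PBS. As means of log2(TPM + 1), the oocyte list stood at 4.34 and 1.85 in the libraries labelled young PBS, at 4.93 in both labelled old PBS, and at 2.82 and 2.16 in those labelled old MIT-001. The granulosa list stood at 5.92 and 5.25, at 7.11 and 7.61, and at 5.92 and 6.20 in the same order. The plasma cell list stood at 5.46 and 3.59, at 2.21 and 2.11, and at 5.40 and 3.18. The submitters' codes for these libraries, CTL for those labelled young PBS and Nor for those labelled old PBS, state no age and do not settle which group is the older. All groups below are therefore named as labelled, and every direction between ages or treatments holds for the libraries as labelled only.

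**Figure D1:**
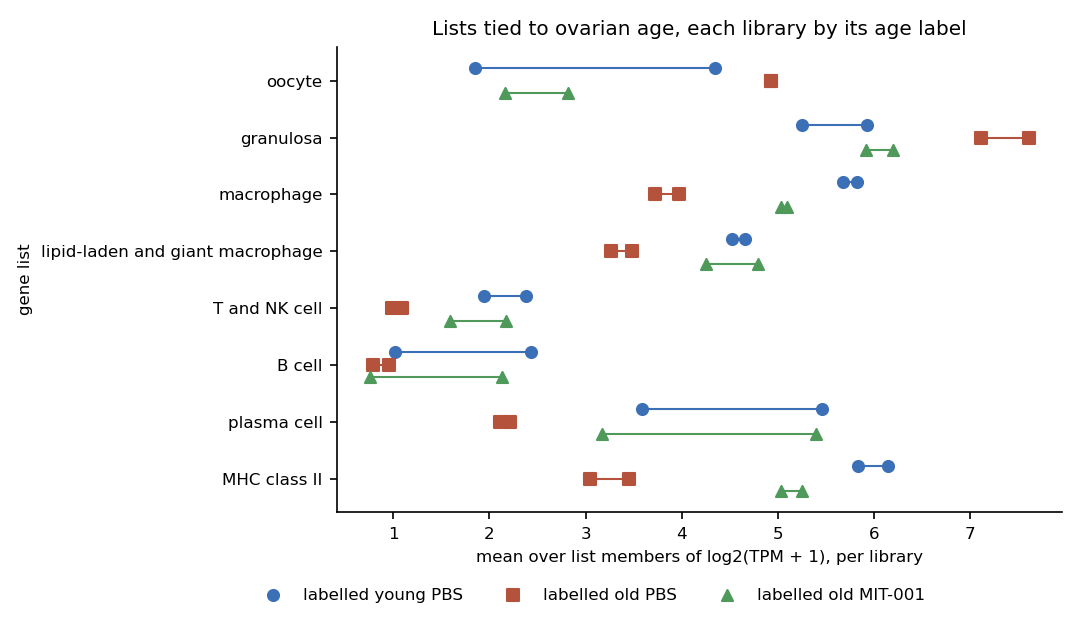
Mean of log2(TPM + 1) over the members of 8 gene lists (x axis), one point per library and a line joining the 2 libraries of a group, with groups as labelled. The libraries labelled old PBS have the highest oocyte and granulosa values (4.93 in both for oocyte genes) and lower macrophage and MHC class II values than the other 4 libraries.

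The comparison of the libraries labelled old PBS with those labelled young PBS addresses what differs with age in the ovary without treatment. By camera with a preset correlation, the oocyte and granulosa lists were higher and most immune lists lower in the libraries labelled old PBS, while the theca and ovulatory cumulus lists did not pass. No list passed camera with an estimated correlation (smallest adjusted p 0.081). Inhba, which encodes the activin A subunit made by granulosa cells, rose by a log2 fold change of 4.44 ± 0.35 (SE), from 10.3 ± 2.26 TPM to 254 ± 114 TPM (SD, n = 2 each). H2-Eb1, an MHC class II beta chain that presents antigen, had a log2 fold change of -5.26 ± 0.22, from 94.0 ± 14.9 TPM to 1.46 ± 0.10 TPM. The complement genes C1qa and C1qc, expressed by macrophages, had log2 fold changes of -2.61 ± 0.20 and -2.54 ± 0.20. Igha, the constant region of immunoglobulin A, had a log2 fold change of -4.39 ± 0.32.

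These 5 genes and Trib2, a pseudokinase gene at 37.6 ± 5.03 TPM in the libraries labelled young PBS and 195 ± 3.61 TPM in those labelled old PBS (log2 fold change 2.35 ± 0.19), were the 6 of 16473 genes past limma's test at the adjusted threshold of 0.05. The adjusted p was 0.00525 for H2-Eb1 and 0.0433 for the other 5. On mm10, Inhba (Gene ID 16323) lies on chromosome 13 from 16004256 to 16031609 on the plus strand, and H2-Eb1 (14969) on chromosome 17 from 34305867 to 34316674, also on the plus strand. Trib2 (217410) spans 15791725 to 15816962 of chromosome 12, and Igha (238447) spans 113256204 to 113260236 of the same chromosome. C1qa (12259) and C1qc (12262) are neighbours on the minus strand of chromosome 4, from 136895916 to 136898844 and from 136889801 to 136892936.

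Genes with large changes that did not pass included Grem1, a BMP antagonist (log2 fold change 3.41 ± 0.35), Rasd2 (2.97), Mro (2.91) and AF357359 (2.85). Others were Cyp17a1, the enzyme of androgen synthesis in theca cells (2.83 ± 0.86), Kcnj16 (2.81), the monoamine transporter gene Slc18a2 (2.81) and Prkar2b (2.78). Glo1-ps at 4.34 and Rps19-ps6 at -7.24 are pseudogenes that can share reads with their parent genes, so their values are uncertain. On the lower side stood Igkc (-5.46 ± 1.33), Car3 (-4.04), Wfdc17 (-3.81), the complement gene C3 (-3.78 ± 0.38) and Wfdc2 (-3.43). The mast cell proteases Mcpt4 (40.3 and 5.14 TPM in the libraries labelled young PBS) and Tpsb2 (30.9 and 5.63 TPM) and the immunoglobulin segment Igkj1 (85.9 and 14.1 TPM) were listed at 0 in both libraries labelled old PBS. The adjusted p of these genes lay between 0.065 for AF357359 and 0.269 for Igkj1.

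Among the 36 gene lists fixed before the data were examined, 21 passed camera with a preset correlation, 6 higher and 15 lower in the libraries labelled old PBS. All 22 oocyte genes were higher, with a median log2 fold change of 2.00, although none passed over all genes and 0 passed when adjusted over the list alone. The members with the smallest p were Tle6 (0.66), the meiotic kinase gene Mos (1.93), Kpna7 (1.87) and Nlrp5 (2.10). The oocyte list had an adjusted p of 2.91e-05 by camera and an adjusted p = 0.546 with an estimated correlation. Of 15 granulosa genes 14 were higher (median 1.70), 1 passed over all genes and 13 when adjusted over the list alone, among them Inhbb (1.70 ± 0.21), the gap junction gene Gja1 (1.96) and Hsd17b1 (1.08). The granulosa list had adjusted p = 0.269 with an estimated correlation. The 24 proliferation genes were all higher (median 1.11, with Top2a at 1.59 and Rrm2 at 1.12), as were 18 of 19 cholesterol synthesis genes (median 0.77, with Sqle at 1.10). When adjusted over the list alone 0 and 2 of them passed, and the adjusted p = 0.504 and 0.423 with an estimated correlation. Erythroid genes (median 0.89) and genes of DNA double-strand break repair (0.60) also passed, with adjusted p = 0.546 for each with an estimated correlation. The size of the oocyte difference rested on single libraries: its median was 3.47 without replicate 1 labelled young PBS, where 19 oocyte and 9 granulosa genes passed over all genes, and 0.62 without replicate 2. Proliferation genes had a median of 0.64 without replicate 2 labelled young PBS. The erythroid list did not pass without replicate 1 labelled young PBS (0.42) or without replicate 1 or 2 labelled old PBS (0.94 and 0.84), and the repair list did not pass without replicate 1 or 2 labelled young PBS (0.96 and 0.38) or replicate 2 labelled old PBS (0.39).

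Most immune lists were lower. The macrophage list was lower in 12 of 12 members (median -2.0), 2 passed over all genes and 10 when adjusted over the list alone, with C1qb at -2.54 ± 0.23 and Cd68 at -2.33. The 7 MHC class II genes were all lower (median -3.11), 1 passed over all genes and all 7 when adjusted over the list alone, with H2-Ab1 at -3.32, H2-Aa at -3.11 and Cd74, the invariant chain, at -3.11. Of 14 complement genes 13 were lower (median -1.48), 2 passed over all genes and 12 when adjusted over the list alone, with C4b at -3.37. These lists had adjusted p = 0.164, 0.168 and 0.081 with an estimated correlation, and they were the 3 lists past fry, at adjusted p 0.00959, 0.00959 and 0.00936. Plasma cell genes had a median of -3.05 (Ighg2c -3.67), cytokines and chemokines -1.70 (Ccl12 -1.94, Ccl7 -3.31), lipid-laden and giant macrophage genes -1.57 (Trem2 -2.61, Acp5 -1.34), T and NK cell genes -1.22 (Ccl5 -1.69, Cd3e -1.62), and B cell genes -0.78. When adjusted over the list alone, 3, 8, 7, 4 and 0 of their members passed, and the adjusted p = 0.269, 0.169, 0.168, 0.222 and 0.453 with an estimated correlation. The inflammasome list (median -0.68, Casp1 -1.60) and the interferon list (-0.53, Gbp2 -1.22) had 1 and 3 members past when adjusted over the list alone, and adjusted p = 0.168 and 0.269 with an estimated correlation. Without replicate 1 labelled young PBS the medians were -1.58 for plasma cell genes, -0.98 for cytokines and 0.12 for B cell genes, which then did not pass. Without replicate 2 labelled young PBS they were -2.72 for cytokines, -1.30 for B cell, -1.15 for inflammasome and -0.90 for interferon genes.

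Markers of other tissues and of handling moved with the same groups. All 11 surface epithelium genes were lower (median -0.55, 4 when adjusted over the list alone, with Krt18 at -1.08 and Upk3b at -1.22), as were 10 of 10 oviduct and ciliated genes (median -1.12) and 5 of 6 adipocyte genes (median -2.14). The 16 genes of the dissection and handling response, mostly immediate early genes, were all lower (median -1.14, 3 when adjusted over the list alone, with Fosb at -2.55 and Atf3 at -2.63). These 4 lists had adjusted p = 0.168, 0.423, 0.269 and 0.269 with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of -0.12, with 53 of 75 lower and adjusted p = 0.376 with an estimated correlation. Theca and interstitial genes did not pass camera (median 0.33, adjusted p 0.311), with Insl3 at 2.55 and Lhcgr at 1.37, nor did ovulatory cumulus genes (median 0.0028, 4 of 8 higher, adjusted p 0.209), the antioxidant list (median 0.08, Cat 0.74), the senescence list (0.08, Cdkn2a -2.93) or the smooth muscle list (-0.13, Des -3.0). The adipocyte median was -0.51, and did not pass, without replicate 1 labelled young PBS, and was -4.08 without replicate 2. The handling median was -0.73 and -1.88 in the same order, and that of nuclear oxidative phosphorylation -0.03 (not past) and -0.19, or -0.03 without replicate 2 labelled old PBS. The surface epithelium median was -1.07 without replicate 1 labelled young PBS, and -0.87 and -0.84 without replicate 1 or 2 labelled old PBS.

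At an unadjusted p below 0.05, 2404 genes were higher and 584 lower, but the split followed the scaling. Of these, 80.5% were higher with TPM as deposited, 62.6% with FPKM, 52.7% after quantile normalization and 36.2% after centring each library on its median. Centring moved the median log2 fold change of all genes from 0.23 to -0.09. The count of 6 rested on single libraries. It was 948 without replicate 1 labelled young PBS, 14 without replicate 2 labelled young PBS, 0 without any 1 of the other 4 libraries, and 0 when only the 4 PBS libraries were fitted.

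**Figure D2:**
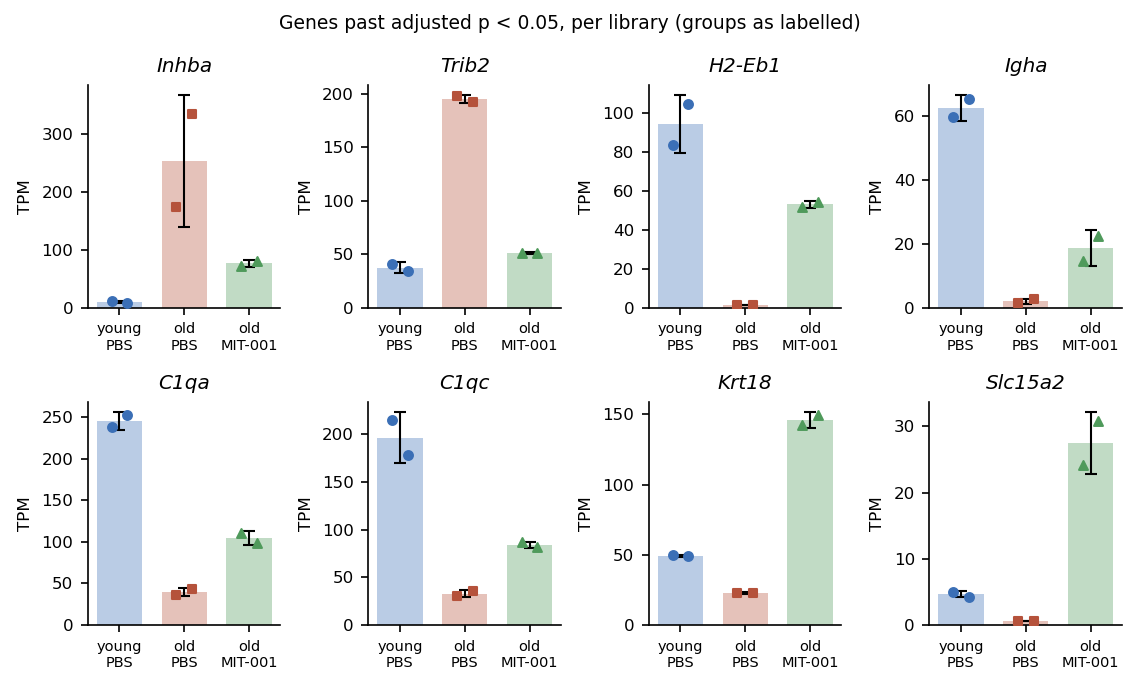
TPM of the 8 genes past an adjusted p of 0.05 in any comparison (y axes start at 0), with a point per library, bars for group means and error bars for the SD of 2 libraries, groups as labelled. H2-Eb1 lies at 1.39 and 1.53 TPM in the libraries labelled old PBS and at 51.7 TPM or more in the other 4.

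The comparison of the libraries labelled old MIT-001 with those labelled old PBS addresses what the compound changes in old ovaries. By camera with a preset correlation, the surface epithelium and most immune lists were higher, and the oocyte, granulosa and proliferation lists lower, in the libraries labelled old MIT-001. With an estimated correlation no list passed camera (smallest adjusted p 0.175). Limma called 3 genes, all higher. H2-Eb1 rose by a log2 fold change of 4.45 ± 0.22 to 52.9 ± 1.64 TPM (adjusted p 0.0144). Krt18, a keratin of simple epithelia, rose by 2.63 ± 0.18, with 146 ± 5.40 TPM against 22.8 ± 0.47 TPM (adjusted p 0.0343). Slc15a2, a peptide transporter, rose by 4.10 ± 0.29, with 27.4 ± 4.68 TPM against 0.645 ± 0.0225 TPM (adjusted p 0.0343). Krt18 (16668) lies on the plus strand of chromosome 15 from 102028216 to 102032026, and Slc15a2 (57738) on the minus strand of chromosome 16 from 36750161 to 36785158.

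Genes that did not pass but stood highest were BC048679 (5.56 ± 0.63), Plet1 (4.70), Igkc (4.55 ± 1.33), and Wfdc2 (4.19), followed by Pax8, a transcription factor of the oviduct epithelium (4.11), Car3 (4.02), the epithelial adhesion gene Epcam (3.91) and Padi1 (3.86). The lowest were the pseudogene Glo1-ps (-3.45), Rasd2 (-3.22 ± 0.30), Ezhip (-3.13), Padi6 (-3.05), Fbxw24 (-2.96) and the oocyte linker histone H1f8 (-2.96). The zona pellucida genes Zp2 (-2.95) and Zp3 (-2.92), Oas1e (-2.94) and Kcnj16 (-2.88) followed. The adjusted p of these genes ranged from 0.0636 for Rasd2 to 0.382 for Fbxw24.

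Of the 36 lists, 22 passed camera, 14 higher and 8 lower. Oocyte genes were lower in 22 of 22 members (median -2.62, 0 past over all genes and 20 when adjusted over the list alone), with Tle6 at -1.32, Mos at -2.77, Zp1 at -2.71 and Kpna7 at -2.46. Granulosa genes were lower in 14 of 15 (median -1.48, 10 lower when adjusted over the list alone), with Inhbb at -2.12, Hsd17b1 at -1.39, Inhba at -1.63 and Gja1 at -1.48. Over all genes, 17 or 18 oocyte and 5 granulosa genes passed without replicate 1 or 2 labelled young PBS, and 17 and 5 when only the 4 libraries compared were fitted. Kitl, the KIT ligand, passed in the other direction when adjusted over the list alone. Proliferation genes had a median of -1.17 (16 of 24 when adjusted over the list alone, with Plk1 at -1.59 and Aurka at -1.55), cholesterol synthesis genes -0.77 (19 of 19 lower, Sqle -1.26) and theca and interstitial genes -0.75 (11 of 11 lower, Insl3 -1.36). These 5 lists had adjusted p = 0.347, 0.258, 0.358, 0.258 and 0.376 with an estimated correlation. Endothelial genes (median -0.32, Cdh5 -0.75), nuclear genes of oxidative phosphorylation (-0.13) and the antioxidant list (-0.22, with the catalase gene Cat at -0.60 and Sod3 at -0.97) were also lower, with adjusted p = 0.358, 0.447 and 0.293 with an estimated correlation and 0 members past when adjusted over the list alone. These 3 lists did not keep their call without each library: endothelial genes did not pass without replicate 2 labelled old MIT-001 (median -0.20), nor did oxidative phosphorylation without replicate 1 labelled old PBS (-0.05, and -0.22 without replicate 2). The antioxidant list did not pass without replicate 1 labelled old MIT-001 (-0.19) or replicate 1 labelled old PBS (-0.23).

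Surface epithelium genes were higher in 11 of 11 members (median 1.89, 1 past over all genes and 10 when adjusted over the list alone), with Krt7 at 2.98 ± 0.30, Upk3b at 2.07 and Krt19 at 2.09. The oviduct and ciliated list had a median of 2.29, with Pax8 and Ovgp1, the oviduct glycoprotein gene (3.76), past when adjusted over the list alone. Its ciliated-cell genes were high in a single library: Foxj1 stood at 67.0 TPM in replicate 2 labelled old MIT-001 and at 0.867 TPM in replicate 1. The list's median was -0.12, and did not pass, without replicate 2, and was 4.01 without replicate 1. The MHC class II list (median 1.81, 6 of 7 when adjusted over the list alone, H2-Aa 1.98, H2-Ab1 1.96, Cd74 1.81), the macrophage list (1.16, 10 of 12, C1qa 1.39, C1qc 1.33, Cd68 1.36) and the complement list (1.02, 7 of 14, C3 3.25, C4b 2.75) were higher. The adjusted p = 0.175, 0.358, 0.258, 0.258 and 0.175 with an estimated correlation for these 5 lists in that order. The surface epithelium, MHC class II, macrophage and complement lists passed fry at adjusted p 0.0207, and stromal fibroblast genes at 0.0412 (median 0.60, Pdgfra 0.93 and Dcn 1.61, adjusted p = 0.293 with an estimated correlation). Stromal fibroblast genes did not pass camera without replicate 2 labelled young PBS, at the same median.

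Plasma cell genes (median 2.22, Igha 2.66, Ighg2c 3.44), lipid-laden macrophage genes (1.44, Ctsk 2.34, Trem2 1.48), cytokines (1.28, Cxcl9 1.27, Ccl7 3.04), and inflammasome genes (1.04, Casp1 1.46, Aim2 2.20) were higher too, as were T and NK cell genes (0.96), ovulatory cumulus genes (0.81, Tnfaip6 1.61, Ptgs2 1.60) and interferon genes (0.54, Gbp2 1.71). In that order, when adjusted over the list alone, 1, 4, 0, 3, 0, 0 and 1 of their members passed, and the adjusted p = 0.378, 0.258, 0.293, 0.258, 0.359, 0.453 and 0.378 with an estimated correlation. Without replicate 1 labelled old MIT-001 the medians were 1.19 for plasma cell, 0.91 for lipid-laden macrophage, 0.64 for T and NK cell and 0.49 for interferon genes, which then did not pass. The interferon median was 1.02 without replicate 2. Beside these groups, the handling response was higher in 16 of 16 genes (median 1.71, 12 when adjusted over the list alone, Fosb 3.54, Atf3 3.60, Nr4a1 1.85, Jun 1.71). Its adjusted p = 0.303 with an estimated correlation.

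At an unadjusted p below 0.05, 1227 genes were higher and 719 lower, 63.1% higher with TPM as deposited against 52.5% after median centring and 45.6% after quantile normalization. The count of 3 became 356 (201 higher and 155 lower, the 3 genes among them) when only the 4 libraries compared were fitted. It was 358 or 372 without replicate 1 or 2 labelled young PBS, and was 0 without any 1 of the 4 libraries compared.

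The comparison of the libraries labelled old MIT-001 with those labelled young PBS addresses what still differs between treated old ovaries and young ones. No gene passed limma's test (smallest adjusted p 0.161), while 2954 genes had an unadjusted p below 0.05, of which 2820 were higher. This share of 95.5% was 83.3% with FPKM, 63.5% after quantile normalization and 44.2% after median centring. The median log2 fold change of all genes was 0.24, and -0.17 after median centring. Surface epithelium genes were higher in 11 of 11 members (median 1.12, 8 when adjusted over the list alone), with Krt18 at 1.55 ± 0.18, Krt7 at 1.97 ± 0.30, Upk1b at 1.34 and Msln, mesothelin, at 1.29. It was the 1 list higher by camera with a preset correlation, with 14 lists lower relative to the other genes. None of these lists passed camera with an estimated correlation (smallest adjusted p 0.276).

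Macrophage genes were lower in 10 of 12 (median -0.72, 5 when adjusted over the list alone, with C1qa at -1.22, C1qb at -1.40, C1qc at -1.21 and Cd68 at -0.97). MHC class II genes were lower in 6 of 7 (median -1.04, 5 when adjusted over the list alone, with H2-Ab1 at -1.36, Cd74 at -1.30, H2-DMa at -1.04 and H2-Eb1 at -0.81), and complement genes in 13 of 14 (median -0.57, 3 when adjusted over the list alone). The adjusted p = 0.35 with an estimated correlation for the surface epithelium, macrophage and MHC class II lists, and 0.276 for complement. Adipocyte (median -0.80), endothelial (-0.31, Cldn5 -0.63), cytokine (-0.25), T and NK cell (-0.22), nuclear oxidative phosphorylation (-0.22, 62 of 75 lower, Ndufs3 -0.49) and lipid-laden macrophage genes (-0.05, Trem2 -1.13) passed camera as lower. They had adjusted p = 0.389, 0.401, 0.542, 0.542, 0.35 and 0.542 with an estimated correlation and 0 members past when adjusted over the list alone. The antioxidant (median -0.02, Gclc 1.05), cholesterol synthesis (-0.09) and proliferation (-0.07) lists also passed as lower, but the means of their members were above 0 (0.0028, 0.0060 and 0.01), and their adjusted p = 0.35, 0.75 and 0.793 with an estimated correlation. The oocyte list (median -0.61, 22 of 22 lower, Tle6 -0.66) and the plasma cell list (-0.23, Igha -1.73, 1 when adjusted over the list alone) had adjusted p = 0.75 each with an estimated correlation.

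Without each library in turn, 6 of these 15 lists kept their call by camera: surface epithelium, macrophage, MHC class II, complement (median -0.87 without replicate 1 labelled old MIT-001), endothelial (-0.15 without replicate 2 labelled old MIT-001) and nuclear oxidative phosphorylation (-0.11 without replicate 1 labelled young PBS). The medians of 8 others changed sign. Without replicate 1 labelled young PBS they were 0.72 for oocyte, 0.64 for plasma cell, 0.41 for cytokine, 0.33 for proliferation, 0.22 for adipocyte, 0.19 for T and NK cell and 0.02 for cholesterol synthesis genes. Without replicate 2 labelled old MIT-001 they were 1.29 for plasma cell, 0.20 for lipid-laden macrophage, 0.10 for cholesterol synthesis and 0.04 for T and NK cell genes, and proliferation genes had a median of 0.15 without replicate 1. By camera, oocyte and proliferation genes turned to higher without replicate 1 labelled young PBS, and plasma cell genes without replicate 2 labelled old MIT-001. Without replicate 2 labelled young PBS the medians were -2.74 for adipocyte, -1.91 for oocyte, -1.30 for plasma cell, -1.24 for cytokine and -0.42 for T and NK cell genes. Without replicate 1 labelled old MIT-001 they were -1.43 for plasma cell, -0.93 for oocyte (-0.33 without replicate 2), -0.77 for adipocyte (not past), -0.54 for T and NK cell and -0.22 for cholesterol synthesis genes. The lipid-laden macrophage list passed only without replicate 1 labelled old MIT-001 (-0.46), and the antioxidant list did not pass without replicate 1 or 2 labelled young PBS (-0.07 and -0.04) or replicate 1 labelled old MIT-001 (-0.10).

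The genes with the largest differences, none of which passed, were BC048679 (3.83), Ppp2r2b (3.32), Cldn22 (3.0) and the matrix proteoglycan genes Ogn (2.97) and Omd (2.75). Also on the higher side were Fndc7 (2.84), Inhba (2.81 ± 0.35), Cdkl1 (2.79), Calb1 (2.74) and Plet1 (2.71). On the lower side were Igkv16-104 (-2.61), Clec4a3 (-2.0), Clec4a1 (-1.98), Ighj1 (-1.77), the Fc receptor chain gene Fcer1g (-1.72), Lst1 (-1.69), Gngt2 (-1.60) and Pld4 (-1.46). The ribosomal protein copies Rps3a3 (-6.24) and Rps3a2 (-2.95) can share reads with their near-identical relatives and are uncertain.

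**Figure D3:**
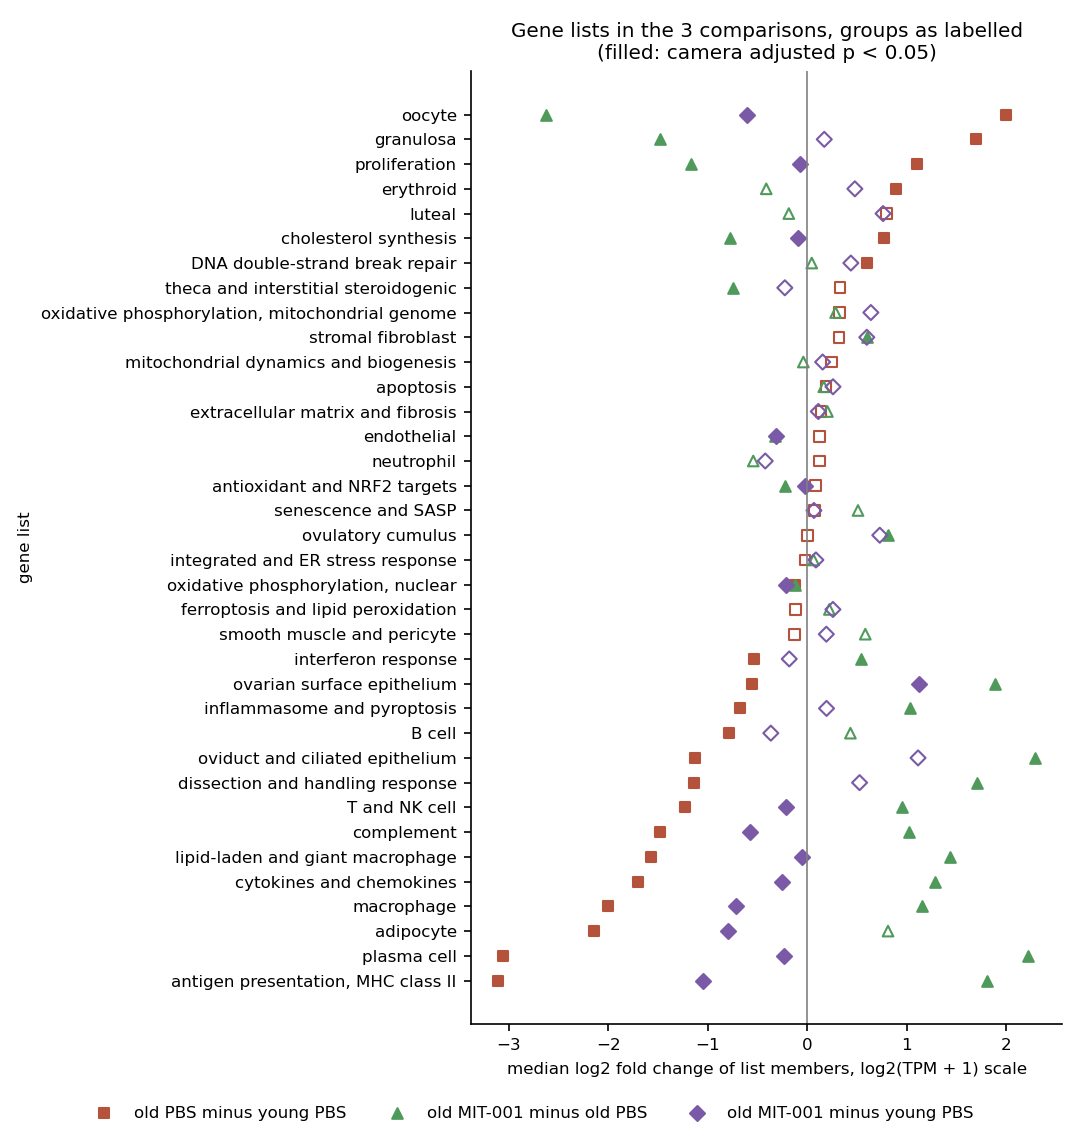
Median log2 fold change of the members of each of 36 gene lists (x axis, log2(TPM + 1) scale) in the 3 comparisons, groups as labelled, with filled symbols where camera's adjusted p was below 0.05. Oocyte genes lie at 2.00 for old PBS minus young PBS and at -2.62 for old MIT-001 minus old PBS, and MHC class II genes at -3.11 and 1.81.

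The last comparison asks whether the treatment difference opposes the age difference, as labelled. Across 16473 genes, which are not independent replicates, the log2 fold changes of old PBS minus young PBS and of old MIT-001 minus old PBS had a Pearson correlation of -0.625. Both use the libraries labelled old PBS, and 1000 simulations of unchanged groups gave a mean of -0.500 (from -0.543 to -0.464). The covariance was -0.286 against -0.0884 in the simulations, a difference of -0.198, and 62.6% of genes had opposite signs against 66.7% in the simulations. At an unadjusted p below 0.05, 487 genes were higher in the first comparison and lower in the second, where independent lists would share 105 and 100 simulations of unchanged groups shared 98.9 on average. Another 359 were lower and then higher, where independent lists would share 43.5 and the simulations shared 99.95. The independent value leaves out the shared libraries and the simulated value leaves out real effects. Simulated genes varied independently, while genes of some lists vary together (estimated correlation 0.92 for oocyte and 0.78 for proliferation genes). The simulated ranges are therefore too narrow to establish an excess. Inhba, Inhbb, Mos and Tle6 were among the genes higher and then lower, and H2-Eb1, C1qa, C3 and Igkc among those lower and then higher. Part of any excess may come from the shared libraries, since splitting them would leave 1 library on each side. Without replicate 2 labelled old PBS there was no excess of shared genes (140 and 147, against 152 and 146 in 20 simulations), the correlation was -0.642 against -0.667, and the covariance difference was -0.0999. Without replicate 1 labelled old PBS 217 and 181 genes were shared against 142 and 150, with correlations of -0.693 and -0.665. The counts were 909 and 623 without replicate 1 labelled young PBS (83.1 and 86.8 simulated), 586 and 542 without its replicate 2 (81.7 and 84.0), and 207 and 197 or 270 and 296 without replicate 1 or 2 labelled old MIT-001 (76.8 to 79.6).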

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

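These alternatives were set before the data were examined. Genes named by the fixed rule had no overlap between the groups' libraries, so leaving out or weighting libraries could not turn their direction. The lists counted here are the 58 list results that already passed camera as reported. All 165 fold changes of named genes kept their direction in each of 2786 gene and setting combinations, and lists kept camera's direction and call in 904 of 1041 combinations, kept only its direction in 134 and turned in 3. The median of a list had the other sign in 16 of the 1041, 14 of them with a library left out. The 3 that turned were in the comparison of old MIT-001 with young PBS, as labelled. With a library left out, the median log2 fold change ranged from -1.91 to 0.72 for oocyte genes and from -0.34 to 0.33 for proliferation genes (highest without replicate 1 labelled young PBS). For plasma cell genes it ranged from -1.43 to 1.29 (highest without replicate 2 labelled old MIT-001). Counts of changed genes were less stable. For old PBS against young PBS (6 genes) the count was 1 without a filter, 11 with FPKM, 15 with median centring, 17 with quantile normalization, 1 without a trend and 1 with array weights. It was 0 with only the 2 groups compared, 36 at an adjusted p below 0.10, and from 0 to 948 with a library left out (948 without replicate 1 and 14 without replicate 2 labelled young PBS). For old MIT-001 against old PBS (3 genes) it was 0 without a filter, 1 with FPKM, 1 with median centring, and 697 with array weights. It was 356 with only the 2 groups compared, 82 at an adjusted p below 0.10, and from 0 to 372 with a library left out. For old MIT-001 against young PBS limma called 0 genes under each alternative, with 2954 at an unadjusted p below 0.05 as reported. Fits that leave out libraries pool the spread over fewer of them, and the cause of these moves was not tested. Lists past camera (21, 22 and 15) fell to 0, 0 and 0 with an estimated correlation and to 3, 5 and 0 by fry, and the third count ranged from 9 (without replicate 1 labelled young PBS) to 18 with a library left out. The correlation of the opposed fold changes ranged from -0.69 (without replicate 1 labelled old PBS, -0.67 in simulated unchanged groups) to -0.50 (without replicate 2 labelled young PBS, -0.41 in simulated groups). The groups share replicate numbers, but the deviations of same-numbered libraries correlated at 0.239, 0.00656 and 0.175, all positive yet not all above 0.1, so the numbers were not taken as pairs. With the replicate block the counts of changed genes were 1, 0 and 0. Without counts, depth limits cannot be set per gene.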

Other observations

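The tests in this part were chosen after the values they use had been seen, apart from the comparison of oocyte, granulosa and plasma cell genes between the PBS groups, which was set before the data were examined. The genes named here outside the fixed lists were likewise chosen after their values were seen. Standard errors in this part measure the spread over the genes of a list, not between libraries. Genes of some lists vary together (estimated correlation 0.92 for oocyte genes), so these errors may understate the uncertainty.

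The mast cell protease gene Cma1 stood at 30.4 and 2.56 TPM in the libraries labelled young PBS, at 14.8 and 0.510 TPM in those labelled old MIT-001, and was listed at 0 in both labelled old PBS. Cpa3 stood at 11.03 and 2.13, at 8.38 and 0.439, and again at 0. Ehf, an epithelial transcription factor gene, stood at 25.3 and 16.9 TPM in the libraries labelled old MIT-001 against 1.64 to 3.04 TPM in the PBS libraries. Cftr, a chloride channel gene, stood at 13.6 and 9.46 TPM against 0.841 to 2.11 TPM, and Vtcn1 at 10.3 and 6.76 TPM against 0.053 to 1.34 TPM.

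The pair labelled young PBS was the least alike (correlation across genes 0.917, against 0.976 for the pair labelled old PBS and 0.955 for the pair labelled old MIT-001). With libraries of the other groups, replicate 1 labelled young PBS correlated at 0.919 to 0.940 and its replicate 2 at 0.914 to 0.937. Akr1c18, which inactivates progesterone in the regressing corpus luteum, stood at 425 TPM in replicate 1 and 13608 TPM in replicate 2, and the luteal genes Sfrp4 and Ptgfr at 881 against 6279 TPM and 112 against 716 TPM. Of the fat cell genes, Adipoq (21.5 against 1.05 TPM), Cfd (77.2 against 3.49 TPM) and Fabp4 (161 against 7.10 TPM) went the other way. So did Retn (19.0 against 0 TPM), Cidec (5.56 against 0.788 TPM) and, at lower values, Lep (1.26 against 0.097 TPM), Pck1 (0.805 against 0.024 TPM) and Ucp1 (0.063 against 0 TPM). Plin1 (9.16 against 19.2 TPM) and Plin4 (110 against 329 TPM) did not. H2-Ea, an MHC class II alpha chain gene, stood at 43.5 TPM in replicate 2 labelled old MIT-001 and between 0.565 and 3.88 TPM in the other 5 libraries.

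In all 8 of 8 lists tied to ovarian age, both libraries labelled young PBS lay on the aged side of both labelled old PBS, with lower oocyte and granulosa and higher immune values, which restates the pattern. The group mean of the libraries labelled old MIT-001 lay nearer that of young PBS in 8 of 8, but replicate 2 lay nearer old PBS for 3 (T and NK, B and plasma cell genes). Scaling of the libraries is argued against, since a factor per library moves all genes alike. Mean log2 changes from young PBS to old PBS were taken in each of the 4 pairs of an old PBS and a young PBS library. That of oocyte and granulosa genes lay above that of immune genes by at least 2.89. In the pair with the smallest gap the changes were 0.83 and -2.06 (2 standard errors over genes of the gap were 0.52). These are the lists of the pattern, so the gap restates it and is not separate support. Relative to the libraries labelled old PBS, oocyte genes in replicate 2 labelled young PBS lay at a mean log2 of -3.08 and theca genes at -0.30. The difference between these 2 changes was -2.78 (2 standard errors over genes were 0.77). Dilution by other tissue alone would lower both alike. Dilution beside more luteal RNA cannot be told apart, since the theca list shares Star, Cyp11a1 and Lhcgr with the luteal list. Luteal genes summed to 45713 TPM there against 31656 and 25072 TPM in the libraries labelled old PBS, though their means of log2(TPM + 1) were alike (9.96 against 9.98 and 9.96). In replicate 1 labelled young PBS the changes of oocyte and theca genes from the libraries labelled old PBS were -0.58 and -1.18. Their difference was 0.60, within 2 standard errors (0.72), so dilution cannot be told apart there. Exchanged age labels between the PBS groups cannot be told apart from a true difference between these animals as labelled, since 0 of 2 lists outside the pattern (senescence and extracellular matrix) separated the groups either way. Under an exchange, the comparison at matched age would be old MIT-001 against the libraries labelled young PBS, in which no gene passed and the macrophage, MHC class II and surface epithelium lists had medians of -0.72, -1.04 and 1.12.

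The surface epithelium list, as a mean of log2(TPM + 1), stood at 5.43 and 5.18 in the libraries labelled old MIT-001 and at 3.31 to 4.36 in the other 4, and Krt7, Krt18, Epcam and Pax8 were each higher in both than in the other 4. Against the libraries labelled old PBS, endothelial genes changed by a mean log2 of -0.29 and surface epithelium genes by 1.90. This difference of -2.20 (2 standard errors were 0.45) argues against loss of follicle tissue raising every other cell type alike. Stromal fibroblast and macrophage genes rose by means of 0.65 and 1.21. Loss of follicle tissue that raised only some cell types was not tested. Ciliated oviduct tissue left on the ovary is argued against for replicate 1, whose 9 ciliated-cell genes lay at -0.52 relative to the PBS libraries (2 standard errors were 0.22), but may have contributed to replicate 2, where they lay at 3.31 (0.89). Ovgp1 and Pax8 were not among these 9 genes. Ovgp1 stood at 567 and 215 TPM in replicates 1 and 2 labelled old MIT-001, against 20.3 to 128 TPM in the PBS libraries. Pax8 stood at 27.9 and 18.3 TPM against 0.178 to 7.06 TPM. Secretory oviduct epithelium, surface epithelium and an effect of the compound were not separated. The handling response list, as a mean of log2(TPM + 1), stood at 7.32 and 7.76 in the libraries labelled old MIT-001. It was lower in those labelled old PBS (6.21 and 5.27), but not in both labelled young PBS (7.56 and 6.43).

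In the libraries labelled old PBS against young PBS, H2-Eb1 had a log2 fold change of -5.26, and the other 6 MHC class II genes a mean of -2.32 (SD 0.98). Fewer cells expressing MHC class II were not tested as an explanation. A strain or haplotype variant is a candidate explanation, though the mice of all groups are given as BDF1. The ratio of H2-Eb1 to H2-Ab1 was 0.433 or more in 4 libraries and 0.0878 or less in those labelled old PBS, at least 4.94 times apart. A variant cannot be told apart from a regulatory difference or a difference in cells, because no reads were used here to read the haplotype.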
